A study of Aspergillus niger with 24 samples.

How the data were processed

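RNA was extracted from hyphae of WT Aspergillus niger CICC2629 and of a TLL-expressing strain of the same background, and libraries were sequenced by standard Illumina methods, per the labels' protocols. The deposited data are a single table of TPM values per gene with a column for each of the 24 libraries, made by the authors. The submitters' processing notes name HISAT2, an aligner, and StringTie and Cufflinks, which assemble and quantify transcripts, without roles, order or versions. The name of the deposited table refers to RSEM, another quantifier, so which tool made the TPM values is not settled by the sources used here. The genome build and annotation are not given in the sources used here. TPM divides each gene's reads by its length and scales each library to a fixed total. A rise of an abundant gene therefore lowers all others, and a gene's value is relative to the library. Depth is unknown, and 0 columns of the table belonged to no sample.

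Libraries were grouped by strain and labelled day, with 3 replicates in each of 8 groups, and the columns were matched to the samples by the library names in the labels. No pair of libraries held identical values, and 659 of the 11846 genes were at 0 in all libraries. The gene IDs were looked up in a reference table of 14404 genes, and 0 matched. The 29 lists of genes written before the data were examined rest on names, products and older locus tags, and 0 of their locus tags matched, so no list was tested and no gene is given a name. A gene listed at 0 may be a failed estimate, so no fold is given against a group at 0 in every library.

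The TPM values were transformed to log2(TPM + 1), a scale that understates changes of genes near 1 TPM. Genes with at least 1 TPM in at least 3 libraries were kept, which left 9558. A model with a mean for each of the 8 groups was fitted to all 24 libraries, with 16 residual degrees of freedom, in limma 3.58.1 (R 4.3.3) with empirical Bayes moderation and a mean-variance trend. Contrasts were the strain difference at each day, its mean over days, the last against the first day within each strain, and the steps between days. Moderated F tests with 3 degrees of freedom were used for the interaction of strain and day and for change across days. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes kept, and a call is an adjusted p under 0.05. Counts of changes of at least 2-fold or 8-fold are on the log2(TPM + 1) scale, among called genes. Abundance classes use the mean TPM over all libraries, with limits at 10, 100 and 1000 TPM, and the side on which each class named in the results lay, higher or lower, was checked under both scalings and did not change. Expected overlaps are the product of both list lengths over the number of genes tested.

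Named IDs followed a rule fixed before the data were examined. For each contrast they are the 2 largest changes each way among genes with an adjusted p under 0.05. A mean of at least 10 TPM in the higher group and no overlap between libraries of both groups were also required. For the mean over days the overlap was judged within every day, a form that the fixed rule did not state. Over all days together, 0 genes had strains without overlap. Any other ID is named as chosen after its values were seen. Principal components were computed on centred log2(TPM + 1) values of the genes kept. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

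The model was tested on simulated data for the 9558 genes, with 100 genes changed by each of both sizes. Noise was drawn with the same spread in all groups for each gene, so the wider spread between the real day 1 libraries is left out. The day 1 shares below therefore may not hold for the real day 1 libraries. At day 1 it recovered 61% of the 2-fold and 82% of the 4-fold changes, with 7.74% of its calls false. At day 2 it recovered 63% and 94%, at day 3 47% and 84%, and at day 4 48% and 88%. For the interaction it recovered 26% and 74%, with 7.41% of calls false. All other simulated genes had no difference in the contrast tested. In the real data 47.1% of genes were called at day 3 and 54.1% at day 4, which makes the Benjamini-Hochberg cutoff less strict. The shares therefore do not give the sensitivity of the real tests. As each gene had the same noise on all days, they do not rank the days by sensitivity either.

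Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5 TPM, no filter and a filter at 5 TPM, median-of-ratios scaling, quantile normalization, a replicate block, library weights, moderation without trend, a fit on the compared libraries alone, and leaving out each library in turn. Alternatives added after seeing the data left out the WT day 3 and TLL day 4 libraries or the day 1 libraries that lay apart, restricted the days, or exchanged the labels of WT days 3 and 4. The labels give each group replicates 1 to 3, but nothing states that a number marks a shared culture or batch.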

Results

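Gene expression was measured by RNA sequencing of mycelium from Aspergillus niger, a filamentous fungus used to make secreted enzymes. The wild type (WT) was compared with a strain of the same background that expressed a lipase named TLL, an enzyme class that cleaves fats and oils. Both strains were grown on potato dextrose agar at 28 °C and sampled on 4 labelled days. Each strain and day had 3 libraries, which gave 24 libraries in 8 groups. The series states its sampling times as 0, 24, 48 and 72 hours and labels its libraries by days 1 to 4 without tying an hour to a day, so the day labels are used. No source says whether replicate libraries came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

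The deposited table listed 11846 genes in TPM, a transcript abundance scaled to gene length and library total. Each library summed to between 999999 and 1000000 TPM. These values keep no record of read number, so the depth of each library is unknown and no counting interval is given. Between 7918 and 8935 genes reached 1 TPM in a library. The most abundant gene of a library held 1.79% to 13.7% of its TPM, and the 10 most abundant genes held 10.2% to 24.1%. Genes were tested with limma on log2(TPM + 1) over the 9558 genes that reached 1 TPM in at least 3 libraries. The files do not pair the gene IDs with names or products, so at most 2 IDs that rose and 2 that fell are given for each comparison. The IDs name no lipase, so the level of the introduced gene was not analysed here and the strain labels were not checked with it.

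The first principal component of the 24 libraries held 41.0% of the variance and set day 1 apart from the later days. The groups averaged 76.0 ± 13.7 in WT day 1 and 84.3 ± 19.0 in TLL day 1 (SD, n = 3 each), and every later group averaged below 0. The second component held 25.0% of the variance. It placed WT day 3 at 63.1 ± 2.95 and TLL day 4 at 53.6 ± 1.14, while WT day 4 lay at -33.2 ± 2.71 and TLL day 3 at -16.9 ± 3.56 (SD, n = 3 each). The third component, with 9.51% of the variance, parted WT day 3 (-44.9 to -43.5) from TLL day 4 (43.03 to 46.2). Mean correlations across genes were 0.910 between WT day 3 and TLL day 4, 0.919 between TLL day 3 and TLL day 4 and 0.971 between WT day 4 and TLL day 3. Correlations across genes between replicates were 0.983 to 0.992 in all groups of days 2 to 4. At day 1 they were as low as 0.923 in WT and 0.920 in TLL, and WT replicate 1 and TLL replicate 3 lay away from the rest of their groups. These 2 libraries correlated with each other at 0.972.

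**Figure D1:**
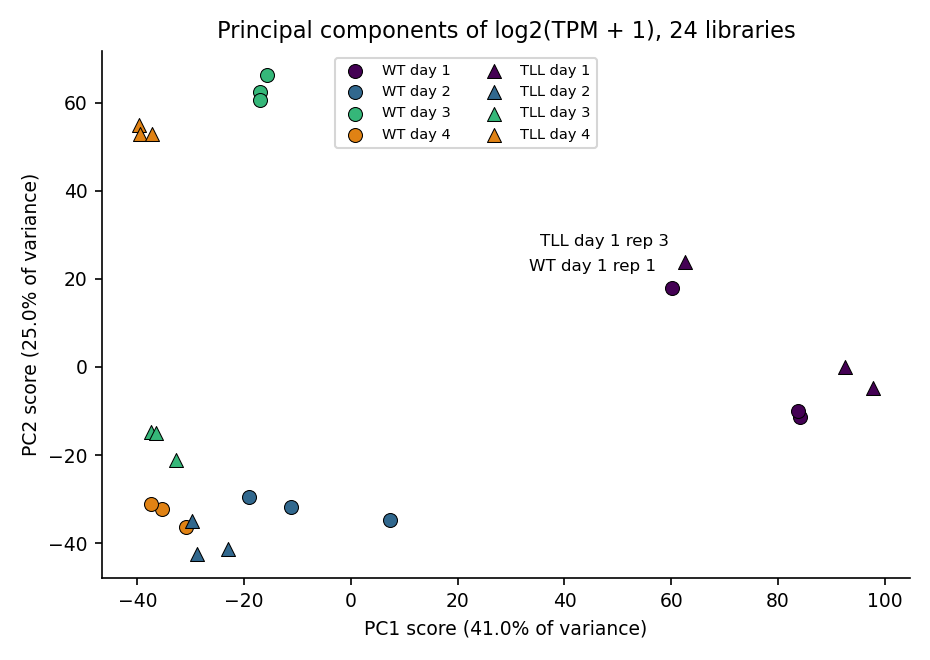
Scores of the 24 libraries on the first (x axis, 41.0% of variance) and second (y axis, 25.0% of variance) principal components of log2(TPM + 1), without unit; circles are WT, triangles TLL, and colours the labelled days. The 3 WT day 3 and the 3 TLL day 4 libraries lie at the top, with means of 63.1 and 53.6 on the second component, and the 2 day 1 libraries away from their groups are named.

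At day 1 most genes called between the strains were lower in TLL. Of 9558 genes, 168 were higher and 531 lower in TLL. Changes of at least 2-fold were found in 17 genes that were higher and 233 that were lower. Of the 169 genes with a mean over 1000 TPM, 16 were called, all of them lower in TLL. The ID NRRL3_01267 averaged 1.89 ± 3.28 TPM in TLL and 67.2 ± 48.7 TPM in WT, a log2 change of -4.88 (SE 0.65, limma adjusted p = 0.000152). NRRL3_02994 fell to 6.52 ± 0.964 TPM from 330.3 ± 278 TPM (log2 change -4.39, SE 0.76, limma adjusted p = 0.00184), where WT replicate 1 held 15.37 TPM. Without a single library the log2 change of NRRL3_02994 ranged from -6.02 (WT replicate 1) to -3.50 (WT replicate 2). That of NRRL3_01267 was weakest without WT replicate 3, at -4.33. In TLL only replicate 1 held NRRL3_01267 above 0, at 5.68 TPM, so no change is given without that library. NRRL3_06626 rose to 38.8 ± 9.41 TPM from 15.6 ± 2.24 TPM (log2 change 1.25, SE 0.25, limma adjusted p = 0.00425). NRRL3_06090 averaged 687 ± 158 TPM in TLL and 316 ± 205 TPM in WT (log2 change 1.45, SE 0.39, limma adjusted p = 0.0294). The call of NRRL3_06090 was lost without TLL day 1 replicate 1 or replicate 2, and its log2 change was 0.64 without WT day 1 replicate 1. Errors of TPM values are SD over n = 3 libraries.

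Scaling the TPM by the median of ratios gave 344 higher and 591 lower genes at day 1, and quantile normalization gave 368 and 457. A limma fit on the 6 day 1 libraries alone called 0 genes, with 700 at an unadjusted p under 0.05, against 2226 unadjusted in the fit on all libraries. Its smallest limma adjusted p was 0.167, so no gene named for day 1 passed in it. The fit on all libraries shares its residual spread over all groups, and day 1 replicates correlated least. The SE and adjusted p given for day 1 may therefore be too small. Without a single library the 699 calls became 1290 (WT replicate 1), 250 (WT replicate 2), 346 (TLL replicate 1), 207 (TLL replicate 2) or 2206 (TLL replicate 3). They became 2468 without both libraries that lay apart, 340 when WT day 3 and TLL day 4 were left out of the fit, and 4756 with library weights.

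At day 2 most genes called between the strains were higher in TLL. The test called 786 genes higher and 142 lower, of which 176 and 74 changed at least 2-fold. NRRL3_00987 rose to 92.6 ± 20.2 TPM in TLL from 11.9 ± 1.82 TPM in WT (log2 change 2.85, SE 0.24, limma adjusted p = 5.6e-07). NRRL3_08927 rose to 20.1 ± 3.41 TPM from 2.37 ± 0.214 TPM (log2 change 2.63, SE 0.18, limma adjusted p = 6.24e-08), and its mean in the 7 other groups was at most 2.90 TPM. NRRL3_08868 fell to 0.583 ± 0.318 TPM from 13.7 ± 7.64 TPM (log2 change -3.11, SE 0.28, limma adjusted p = 1.44e-06). NRRL3_00745 fell to 12.2 ± 3.96 TPM from 98.3 ± 45.9 TPM (log2 change -2.85, SE 0.43, limma adjusted p = 0.000427). All values are SD over n = 3 libraries.

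The median log2 change of all tested genes at day 2 was 0.19, and 0.02 after median-of-ratios scaling. That scaling gave 318 higher and 234 lower genes, and quantile normalization 362 and 283, so the excess of higher genes depended on the scaling. The 928 calls became 571 without WT replicate 2, 240 without WT replicate 3, 321 without TLL replicate 2 and 375 without TLL replicate 3. They became 522 when WT day 3 and TLL day 4 were left out of the fit, 2802 when the 2 day 1 libraries that lay apart were left out, and 5284 with library weights.

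At day 3 the strains differed in 4505 genes, 47.1% of those tested. In TLL 3078 were higher and 1427 lower, with 75 higher and 95 lower by at least 8-fold. A switch from under 1 TPM in every library of a strain to at least 10 TPM in every library of the other was seen in 27 genes that were on in WT and 4 that were on in TLL. Of the genes with a mean of 100 to 1000 TPM, 640 were higher and 141 lower in TLL, while of the genes under 10 TPM, 590 were higher and 664 lower.

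NRRL3_07276 stood at 361 ± 59.1 TPM in TLL day 3 and 0.887 ± 0.836 TPM in WT day 3 (SD, n = 3 each; log2 change 7.68, SE 0.29, limma adjusted p = 5.58e-14). NRRL3_00669 reached 4245 ± 359 TPM in TLL and 35.8 ± 4.37 TPM in WT (SD, n = 3 each; log2 change 6.86, SE 0.43, limma adjusted p = 1.41e-10). NRRL3_04321 was listed at 0 in all 3 TLL day 3 libraries and at 3285.66, 3550.38 and 3125.84 TPM in WT replicates 1, 2 and 3 (limma adjusted p = 1.29e-14). NRRL3_02940 averaged 0.307 ± 0.305 TPM in TLL and 517 ± 74.8 TPM in WT (SD, n = 3 each; log2 change -8.65, SE 0.28, limma adjusted p = 8.2e-15). Median-of-ratios scaling moved the median log2 change of all genes from 0.19 to -0.01 and gave 2212 higher and 2053 lower genes, and quantile normalization gave 2440 and 1908. When TLL day 3 was set against WT day 4 in place of WT day 3, 1129 genes passed and none of these 4 genes did.

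At day 4 the strains differed in 5175 genes, 54.1% of those tested, in nearly equal numbers each way. In TLL 2611 were higher and 2564 lower, with 99 higher and 113 lower by at least 8-fold. Of the genes with a mean under 10 TPM, 826 were higher and 535 lower in TLL. Of genes with a mean of 100 to 1000 TPM, 251 were higher and 627 lower, and of those over 1000 TPM, 22 were higher and 55 lower. Switches between under 1 TPM and at least 10 TPM in every library were seen in 12 genes on in TLL and 8 on in WT.

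NRRL3_04013 reached 1218 ± 244 TPM in TLL day 4 and 1.24 ± 0.480 TPM in WT day 4 (SD, n = 3 each; log2 change 9.09, SE 0.59, limma adjusted p = 3.17e-10). It averaged 57.2 ± 1.52 TPM in WT day 3 and 20.9 ± 7.56 TPM in TLL day 3. NRRL3_00504 reached 729 ± 146 TPM in TLL and 0.493 ± 0.150 TPM in WT (log2 change 8.92, SE 0.45, limma adjusted p = 8.4e-12). NRRL3_09868 averaged 3.13 ± 0.762 TPM in TLL and 591 ± 146 TPM in WT (log2 change -7.15, SE 0.24, limma adjusted p = 5.26e-14). NRRL3_01627 averaged 1.74 ± 0.330 TPM in TLL and 221 ± 57.4 TPM in WT (log2 change -6.31, SE 0.91, limma adjusted p = 1.09e-05).

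**Figure D2:**
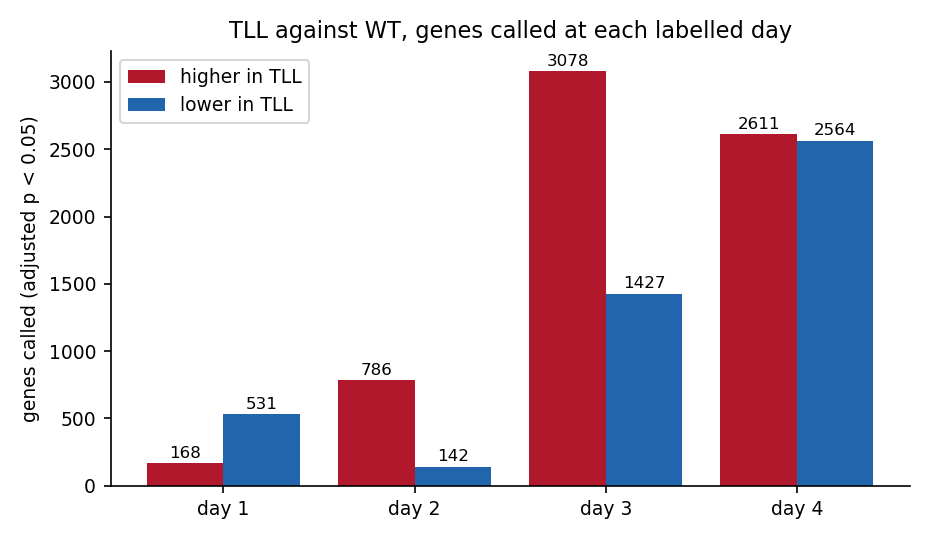
Number of genes (y axis, starting at 0) that passed the limma test between TLL and WT at each labelled day (x axis), with bars for genes higher and lower in TLL and the count above each bar. Day 1 shows 168 higher and 531 lower, day 2 shows 786 and 142, day 3 shows 3078 and 1427, and day 4 shows 2611 and 2564.

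The strain difference depended on the day for 6032 of 9558 genes (limma F test of the interaction), 63.1% of those tested. Most genes called at both day 3 and day 4 changed sides between these days. In TLL 1554 genes were higher at day 3 and lower at day 4, and 670 were lower at day 3 and higher at day 4. Only 298 were higher on both days and 175 lower on both. Independent lists of these lengths would share 826, 390, 841 and 383 genes in the same order. The test of the difference between both days itself called 5591 genes. Across the 9558 genes the strain differences of day 3 and day 4, which share no libraries, correlated at r = -0.44 and rho = -0.45, where genes are not independent replicates. The differences of days 1 and 2 correlated at r = 0.07 and rho = 0.09. Restricted to days 1 and 2, the interaction called 130 genes.

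The gene NRRL3_00669 shows the change of side. It averaged 35.8 ± 4.37 TPM in WT day 3 and 53.9 ± 4.59 TPM in TLL day 4, and 2576 ± 525 TPM in WT day 4 and 4245 ± 359 TPM in TLL day 3 (SD, n = 3 each). NRRL3_07276 averaged 516 ± 30.9 TPM in WT day 4 and 9.03 ± 3.62 TPM in TLL day 4 (SD, n = 3 each), the opposite side from day 3.

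**Figure D3:**
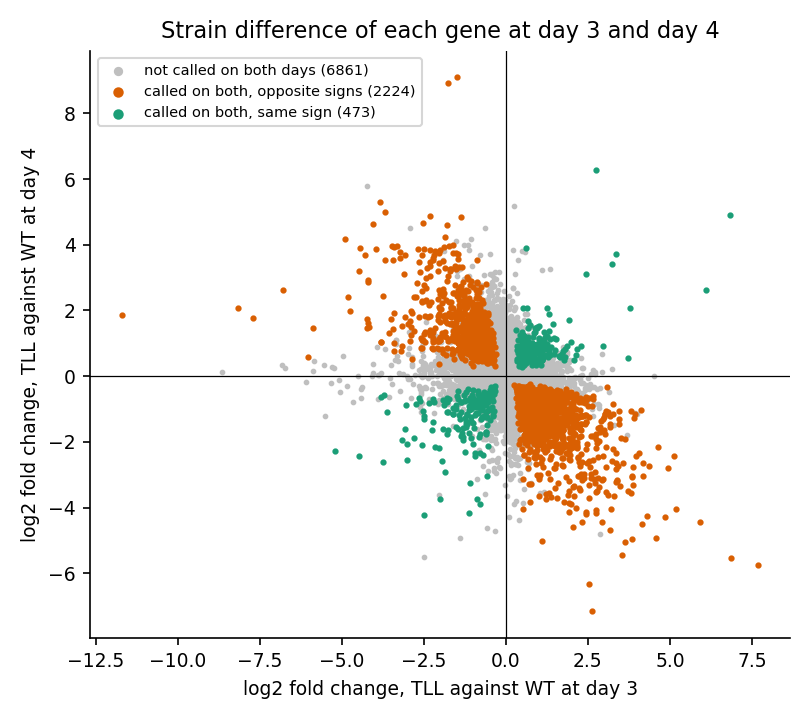
Log2 change between TLL and WT at day 3 (x axis) and at day 4 (y axis) for each of the 9558 genes tested, on the log2(TPM + 1) scale. Orange points are the 2224 genes called on both days with opposite signs, green points the 473 called with the same sign, and grey points all others.

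Averaged over the 4 days, 2594 genes were higher and 1042 lower in TLL, but few by much. The mean difference reached 2-fold in 18 genes that were higher and 97 that were lower. NRRL3_06090 was higher by a mean log2 change of 1.59 (SE 0.20, limma adjusted p = 9.97e-06) and stood at 509 ± 29.0 TPM in TLL day 3 and 66.1 ± 5.01 TPM in WT day 3 (SD, n = 3 each). NRRL3_03038 was higher by 1.41 (SE 0.11, limma adjusted p = 1.57e-08). NRRL3_00745 changed by -1.66 (SE 0.21, limma adjusted p = 1.55e-05) and NRRL3_00183 by -1.53 (SE 0.11, limma adjusted p = 8.39e-09). All TLL libraries lay above all WT libraries of the same day, on each of the 4 days, in 17 genes, and below in 4. If the strains differed on no day, 0.0597 genes would do so each way. That baseline is too low here, as 4505 genes were called at day 3 and 5175 at day 4. It cannot tell a lasting strain difference from separate differences on each day. The 4 genes below became 11 with median-of-ratios scaling and 8 with quantile normalization. Leaving out a library can by construction only keep or raise such counts, and they reached 66 without WT day 1 replicate 3 and 16 without TLL day 1 replicate 3. Median-of-ratios scaling gave 1590 higher and 1626 lower genes and quantile normalization 1946 and 1422. With days 1 and 2 alone, 40 genes passed, and NRRL3_06090 did not.

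Within WT, 7378 genes changed across the days (limma F test). Between day 1 and day 4, 2813 genes rose and 2040 fell, with 266 rising and 79 falling at least 8-fold. Genes over 1000 TPM mostly fell, with 85 lower and 38 higher at day 4. From under 1 TPM in every day 1 library, 43 genes reached at least 10 TPM in every day 4 library, and 9 went the other way. NRRL3_00134 rose to 2077 ± 282 TPM from 3.18 ± 2.05 TPM (log2 change 9.06, SE 0.29, limma adjusted p = 1.82e-15), and NRRL3_09868 to 591 ± 146 TPM from 0.323 ± 0.560 TPM (log2 change 8.86, SE 0.24, limma adjusted p = 1.94e-16). NRRL3_09101 fell to 0.363 ± 0.0945 TPM from 330.6 ± 253 TPM (log2 change -7.27, SE 0.63, limma adjusted p = 7.95e-09). Its neighbour in the ID order, NRRL3_09100, fell to 0.0567 ± 0.0981 TPM from 178.9 ± 122.9 TPM (log2 change -7.00, SE 0.47, limma adjusted p = 1.68e-10). Without WT day 1 replicate 1 these log2 changes were -8.45 and -7.89, and without replicate 2 they were -6.65 and -6.51. All values are SD over n = 3 libraries.

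By the labelled days, the WT step from day 2 to day 3 raised 1926 genes and lowered 3199, and the step from day 3 to day 4 raised 3148 and lowered 1952. Without day 3 the F test across days called 4546 genes. Quantile normalization gave 2336 genes that rose and 2995 that fell between day 1 and day 4, with a median log2 change of -0.12 against 0.06, and a fit on the 6 libraries alone called 3222.

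Within TLL, 7721 genes changed across the days (limma F test). Between day 1 and day 4, 3730 genes rose and 2569 fell, with 331 rising and 97 falling at least 8-fold. Genes over 1000 TPM mostly fell here too, with 95 lower and 51 higher. Switches from under 1 TPM to at least 10 TPM numbered 44, and 14 went the other way. NRRL3_11759 rose to 6006 ± 342 TPM from 7.09 ± 5.84 TPM (log2 change 9.76, SE 0.38, limma adjusted p = 4.83e-14), and NRRL3_04013 to 1218 ± 244 TPM from 2.53 ± 3.50 TPM (log2 change 8.88, SE 0.59, limma adjusted p = 1.61e-10). The log2 change of NRRL3_04013 was 9.67 without TLL day 1 replicate 3 and 8.32 without replicate 1. NRRL3_01340 fell to 0.277 ± 0.242 TPM from 200.6 ± 116 TPM (log2 change -7.15, SE 0.36, limma adjusted p = 2.86e-12), and NRRL3_08061 to 3.13 ± 0.645 TPM from 449 ± 55.4 TPM (log2 change -6.78, SE 0.34, limma adjusted p = 3.13e-12). All values are SD over n = 3 libraries. The step from day 2 to day 3 changed 1710 genes in TLL, and the step from day 3 to day 4 changed 4533. The median log2 change between day 1 and day 4 was 0.20, and -0.09 under quantile normalization, which gave 2982 genes that rose and 3501 that fell.

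From day 1 to day 2, 2037 genes rose in both strains, where independent lists would share 841. These were 93.1% of the 2189 that rose in WT and 55.5% of the 3672 that rose in TLL. Another 638 genes fell in both, where independent lists would share 151, which were 57.5% of the 1109 that fell in WT and 49.2% of the 1298 that fell in TLL. Another 3 genes rose in WT and fell in TLL, and 27 fell in WT and rose in TLL. The changes correlated across genes at r = 0.86 and rho = 0.82. From day 1 to day 4, 2029 genes rose and 1275 fell in both strains, against 1098 and 548 for independent lists, and the changes correlated at r = 0.67 and rho = 0.62. The step from day 3 to day 4 ran the other way. There 1538 genes rose in WT and fell in TLL and 807 fell in WT and rose in TLL, while 250 rose in both and 221 fell in both, and the correlation was r = -0.51 and rho = -0.46. No libraries are shared between the strains in these comparisons, and genes are not independent replicates.

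NRRL3_01765, the gene with the highest mean TPM over all 24 libraries, was singled out after its values were seen. In WT day 1, TLL day 1 and WT day 2 another gene, NRRL3_06779, averaged more, with 18000 ± 7021, 8794 ± 8011 and 35204 ± 6600 TPM against 10430 ± 9733, 5515 ± 5202 and 32203 ± 5017 TPM (SD, n = 3 each). NRRL3_01765 rose in both strains. In WT it reached 122042 ± 13947 TPM at day 4 from 10430 ± 9733 TPM at day 1 (log2 change 3.93, SE 0.50, limma adjusted p = 1.85e-06). In TLL it reached 128657 ± 1972 TPM at day 4 from 5515 ± 5202 TPM at day 1 (log2 change 4.96, SE 0.50, limma adjusted p = 5.26e-08, with SD and n = 3 for each mean). At day 3 it averaged 123317 ± 7367 TPM in WT and 53039 ± 2269 TPM in TLL (SD, n = 3 each), a log2 change of -1.22 that did not pass the test (SE 0.50, limma adjusted p = 0.0529). The day 3 libraries did not overlap, at 114969 to 128907 TPM in WT and 50867 to 55394 TPM in TLL, and the SE is shared by all groups, of which day 1 spread most, from 4777 to 21669 TPM in WT and from 2104 to 11502 TPM in TLL. Its interaction with the day did not pass either (limma adjusted p = 0.347).

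**Figure D4:**
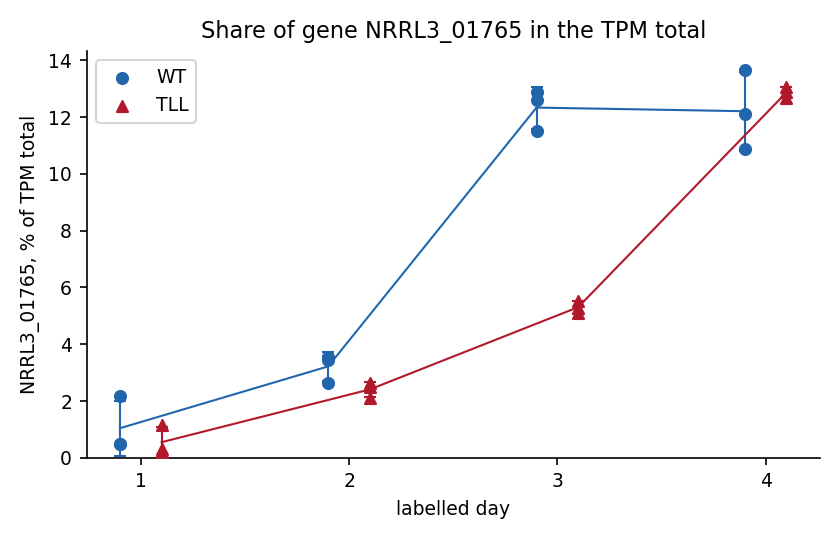
Share of the TPM total (y axis, percent, starting at 0) held by NRRL3_01765 on each labelled day (x axis), with a point per library, lines through the group means and error bars of 1 SD (n = 3). At day 3 the means are 12.3% in WT and 5.30% in TLL, and at day 4 they are 12.2% and 12.9%.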

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

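The tests of exchanged labels, of a common shift and of abundant genes in this part were chosen only after the results were seen, and the splits of the libraries were planned before.

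The strain difference changed with the day in 6032 genes by the interaction test, and the step from day 3 to day 4 differed between the strains in 5591 genes by a test of that difference. Of the genes called at both days, 2224 had opposite signs and 473 the same sign, so that 82.5% changed sides. WT day 3 and TLL day 4 lie together on the second principal component, away from the other groups, but at opposite ends of the third (-44.9 to -43.5 and 43.03 to 46.2). The mean correlation of TLL day 4 with TLL day 3, 0.919, is above that with WT day 3, 0.910.

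A few abundant genes taking more of the TPM total as the cause is argued against by WT day 4, whose 10 most abundant genes hold 20.4 ± 1.04% of the TPM, nearer to WT day 3 (23.3 ± 0.884%) and TLL day 4 (22.2 ± 1.04%) than to TLL day 3 (14.0 ± 1.32%), and which yet averages -33.2 on the second component, below the -16.9 of TLL day 3. TLL day 4 against WT day 3 gave 4593 calls and TLL day 3 against WT day 4 gave 1129. The ratio was 4.07 (3.67 to 8.07 when each library was left out). A shift common to WT day 3 and TLL day 4, such as a library batch, is therefore not their only difference. They differ in strain and labelled day as well, so the ratio cannot decide whether they share a batch. For the part of the difference that these groups share, a batch stays open, and their 6 columns stand first in the deposited table, ahead of the other groups in order. An exchange of the labels of WT days 3 and 4 cannot be told apart from a true difference in timing. With them exchanged, the steps of both strains from day 3 to day 4 correlate across genes at a Spearman rho of 0.463. By construction this is the value of the labelled steps with its sign reversed. Exchanged labels, a true difference in timing, a shared batch or an exchange of the TLL days could each give it. A shift in timing between the strains, in which part of a change seen in WT at day 3 came in TLL at day 4 and was gone from WT by then, stays open as an untested biological hypothesis.

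The real strain and day labels were compared with other splits of the same libraries. For the interaction 2 of 100 splits called as many genes, the real one included, and the other, with 6079 calls, kept the day 3 groups whole, exchanged the day 4 groups whole and mixed the strains at days 1 and 2. A count of this size thus arose in a split with only the day 3 and day 4 groups whole, so it does not single out the real labels. For the mean over days 1 of 100 splits gave as many as 3636 calls, the highest other being 2388, in a split that exchanged the strains at day 2 as whole groups. Across days 1 of 100 gave as many as the 7378 calls of WT (highest other 2444) and 1 of 100 as many as the 7721 of TLL (highest other 4399). No other split drawn gave as many calls for these 3 results. As the replicates may be technical, this compares the groups with the spread of these libraries only and cannot exclude chance differences between cultures.

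For comparisons of 3 against 3 libraries only 10 splits exist, which is too few for a share under 0.05. As many calls as the real labels came from 1 of 10 splits at day 2 (928, highest other 1), day 3 (4505, highest other 1), day 4 (5175, highest other 1), and between day 4 and day 1 of WT (4853, highest other 529). Between day 4 and day 1 of TLL it was also 1 of 10, where the real labels gave 6299 calls and limma gave 0 in every other split, with at most 2892 genes at an unadjusted p under 0.05. At day 1, 4 of 10 splits called as many as the real 699, and the highest other called 2414. That split put WT replicate 1 and TLL replicate 3 on the same side, so the day 1 libraries have a structure that their strains do not give.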

How the results depend on the processing

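The comparisons with WT days exchanged or replaced, with days 1 and 2 alone, without WT day 3, and without the day 1 libraries that lay apart or the WT day 3 and TLL day 4 libraries were chosen only after the results were seen; the others were planned.

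Without single libraries day 1 gave 207 (without TLL replicate 2) to 2206 (without TLL replicate 3), with 1290 without WT replicate 1, 250 without WT replicate 2 and 346 without TLL replicate 1. Day 2 gave 240 (without WT replicate 3) to 1287, with 571 without WT replicate 2, 321 without TLL replicate 2 and 375 without TLL replicate 3. Day 1 gave 0 calls by limma on its 6 libraries alone (700 at an unadjusted p under 0.05), and 2468 without both libraries that lay apart. Fits on 6 libraries leave 4 residual degrees of freedom, and at days 2, 3 and 4 they called 928, 6056 and 5935 genes. The degrees of freedom alone therefore do not account for the 0 calls at day 1. Without WT day 3 and TLL day 4 in the fit, day 1 gave 340 and day 2 gave 522. Without both day 1 libraries in the fit, day 2 gave 2802, and with median-of-ratios scaling 552. Library weights, whose iteration stopped before its tolerance, gave 4756 at day 1, 5284 at day 2, 6820 at day 3 and 6465 for the mean over days. Where the construction above does not show it, the cause was not tested.

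TLL day 3 against WT day 4 gave 1129 calls, and NRRL3_07276 then changed by -0.53. Days 1 and 2 alone gave 40 for the mean and 130 for the interaction, with fewer libraries. WT without day 3 gave 4546, and WT day 4 against day 1 on its 6 libraries gave 3222. With WT days 3 and 4 exchanged, rho of the strain differences of days 3 and 4 became 0.0553. That of both strains' change from day 1 to day 4 became 0.729. That of their step from day 3 to day 4 became 0.463 by construction, since the exchange only reverses the sign of the WT step.

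Leaving out single libraries gave 3867 to 4000 calls at day 3, 4411 to 4861 at day 4, 3162 to 4060 for the mean, 5567 to 6914 for the interaction, 6872 to 7871 across WT days, 4262 to 5427 for WT day 4 against day 1, 7249 to 8053 across TLL days and 5653 to 6653 for TLL day 4 against day 1. The 3 correlations ranged from -0.464 to -0.412, 0.575 to 0.659 and -0.471 to -0.439. Genes of opposite sign at days 3 and 4 numbered 1943 to 2557. Of 556 values of named genes under alternatives, 544 kept direction and call, 11 lost the call and 1 reversed. These genes were chosen from the same data for large called changes without overlap, so this does not measure how stable other calls are.

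With the replicate block the counts were 700, 943, 4522 and 5175 for days 1 to 4, 3683 for the mean, 6032 for the interaction, 7380 and 7745 across WT and TLL days, and 4874 and 6325 for day 4 against day 1. Same-numbered WT and TLL libraries of a day deviated together at over 0.1 in 2 of 12 pairs (r from -0.645 to 0.441). Of the 12 WT libraries, 3 correlated best with their own number in TLL. No pairing of the strains by number was thus seen within a day, and pairing across days was not tested. Gene list tests and their alternatives were not run, as no list matched the IDs, and a fit on the compared libraries alone is the fit itself for the mean and the interaction. Depth is unknown and sets no limit that could be computed.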

Other observations

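The test of neighbouring IDs and the test of day 1 libraries exchanged between strains were chosen only after the results were seen, and the test of day 1 libraries further along towards day 2 was set before its result, its comparison with days 3 and 4 after.

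WT day 3 was the only one of the 8 groups with genes on in it alone, here a mean of at least 10 TPM there and under 1 TPM in each other group. There were 8 such genes, and 0 in each other group, in a search made after the values were seen. NRRL3_02940 averaged 517 ± 74.8 TPM in WT day 3 and at most 0.883 TPM in another group, and NRRL3_11480 averaged 119 ± 55.0 TPM and at most 0.207 TPM (SD, n = 3 each).

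Genes with large changes had neighbouring ID numbers more often than shuffled genes. Among the 570 genes changed at least 4-fold at day 4, 70 neighbouring pairs changed the same way. The mean in 10000 shuffles was 15.1, a ratio of 4.64 (permutation p = 1e-04, the smallest these shuffles can give). At day 3 there were 77 pairs among 528 genes, against 13.0. Between day 4 and day 1 of WT there were 161 among 854 genes, against 41.3. In TLL there were 220 among 1225 genes, against 82.9, and the longest run was 8 genes. If ID numbers follow the order on the chromosomes, which no source used here states, this is consistent with clusters of genes that change together, as a hypothesis. Reads shared between neighbouring copies of a gene could also give such pairs, and this was not tested, as no sequence was used here.

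WT day 1 replicate 1 and TLL day 1 replicate 3 resembled each other more than their groups. Their deviations from the other libraries of their groups correlated across genes at 0.629, and 872 genes deviated over 2-fold the same way in both against 39 in opposite ways. An exchange of these libraries between the strains cannot be told apart, since WT replicate 1 correlated at 0.923 and 0.924 with the rest of WT and at 0.904 and 0.927 with the rest of TLL, and TLL replicate 3 at 0.920 and 0.949 with the rest of TLL and at 0.926 and 0.934 with the rest of WT. Whether both cultures were further along towards day 2 stays open, because their deviations correlated with the other strain's change from day 1 to day 2 at 0.358 (WT replicate 1) and 0.410 (TLL replicate 3), but also with its change to day 3 at 0.385 and 0.445 and to day 4 at 0.429 and 0.284. On the first principal component they lay at 60.2 and 62.6, nearer to day 2 than the rest of day 1, at 83.7 to 97.8. Day 2 averaged -7.65 in WT and -27.2 in TLL there, and days 3 and 4 of each strain lay further below. On the second they lay at 18.0 and 23.7, above the rest of their groups. Day 2 lay below on it, at a mean of -32.0 in WT and -39.6 in TLL. An unrecorded batch that both libraries shared stays open too.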
